A study of Zea mays with 12 samples.

How the data were processed

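Leaves of maize (Zea mays) seedlings were profiled on the Affymetrix GeneChip Maize Genome Array, a 1-colour oligonucleotide array on which a set of short probes reports each transcript. The 12 arrays cover 4 groups of 3, made from the lines Cat100-6 (aluminium-tolerant, per the labels) and S1587-17 (aluminium-sensitive, per the labels), each grown for 3 days in an acid soil of pH 4.1 or in the same soil limed to pH 5.5, which served as the control. Groups and replicate numbers were taken from the sample titles. The source labels of the 6 Cat100-6 samples write Ca100-6, and a description shared by all 12 samples says root leaves. These were read here as Cat100-6 and as leaves. The labels call the samples biological replicates and do not say whether the 3 of a group came from separate soil bags, so that the p-values measure the spread between these samples only.

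The deposited table holds log2 expression values summarised by RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and combines the probes of a set. The software, its version and its settings are not given in the sources used here. Medians per array lay between 7.13 and 7.27 on the log2 scale, so the arrays were close to but not exactly aligned. RMA values carry no detection calls, and differences between dim probe sets are compressed. Arrays have no read depth, and their number limits the precision.

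Of the 17734 probe sets in the table, 113 control probe sets were left out of every test, and 17621 were tested. The platform annotation gave exactly 1 gene symbol to 1452 of the tested probe sets, several to 1 and none to 16168, which are unnamed here. Gene names were updated through the RefSeq gene table of the B73 NAM 5.0 assembly, in which 1377 of those probe sets and 1060 of their 1108 genes were found. A readable name was held by 975 genes. No genome coordinates were used, because the array's design names no build.

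All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean per group and 8 residual degrees of freedom, followed by empirical Bayes moderation. Contrasts were the response to acid soil in each line, the difference of these responses (Cat100-6 minus S1587-17), the difference between lines in each soil (S1587-17 minus Cat100-6), and the mean response over both lines. P-values were adjusted by the Benjamini-Hochberg method over the 17621 probe sets, and an adjusted p under 0.05 counted as passing. Gene lists were tested with limma's camera, which compares a list with all other probe sets, with a preset correlation between genes of 0.01 and, as an alternative, with a correlation estimated per list. The comparisons, the alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined. A total of 22 lists with at least 5 probe sets were tested. The list of circadian clock genes had no member among the named probe sets, and those for the TCA cycle, aluminium tolerance and phosphate transport had too few. List matches of 21 genes were left out because the gene's name showed another function than the list's.

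Within a comparison the text names genes that passed, whose 2 groups of arrays did not overlap, and that were among the 10 highest or the 10 lowest log2 differences, with 1 probe set per gene, that of the highest mean. For the difference of responses, the arrays had to be apart in at least 1 line or the responses had to go in opposite directions. Up to 2 members of each list with the lowest p were added. Where under 5 genes passed, the 10 with the lowest unadjusted p are given as values. Gene symbols with a single character are not printed, and a few other genes that the rule names are not described here.

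The procedure was tested on simulated data in which 50 probe sets were changed at each of 4 sizes. Each probe set kept its residual SD, pooled over the 4 groups, and noise was drawn independently. Correlation between genes, unequal spread of the groups and deviating arrays were therefore not kept. Far fewer probe sets were changed than passed in Cat100-6, so the shares and false calls below describe the simulation only. For the response of Cat100-6, 24% of those changed by 0.5 log2 units, 80% of those changed by 1 and 98% of those changed by 2 were recovered with the true sign, with 9 false calls. For the difference of responses the shares were 4%, 48% and 90%, with 6 false calls. Alternatives were a filter that left out the 40% dimmest probe sets, a second quantile normalization, subtraction of each array's median, a fit of only the 2 groups compared, a trended and robust variance, array weights, the replicate number as a block, a threshold of at least 1 log2 unit, 1 probe set per gene in the list tests, and each array left out in turn. Setting each array to the same mean of the spiked hybridization controls was added after the data were seen. Figures were drawn with matplotlib 3.10.9.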

Results

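Transcript levels were measured in leaves of 2 maize inbred lines that differ in tolerance to aluminium, a metal that becomes soluble and toxic to plants in acid soils. Seedlings of Cat100-6, the tolerant line, and of S1587-17, the sensitive line, were grown for 3 days in acid soil or in limed control soil, and each of the 4 groups was represented by 3 arrays. Values are log2 RMA expression. The first principal component held 66.2% of the variance between arrays and the second 25.1%. Arrays of the same group correlated across probe sets at 0.985 to 0.997 in Cat100-6 and at 0.995 to 0.997 in S1587-17, with 1 exception. S1587-17 control soil replicate 3 correlated with the other arrays of its group at only 0.963 to 0.967, and at 0.950 to 0.953 with Cat100-6 control soil, against 0.902 to 0.914 for its group-mates. It was kept in every main test. The difference between 3′ and 5′ probe sets of 5 control genes, which RNA quality and labelling can both change, was 1.59 ± 0.09 in Cat100-6 control soil and 1.37 ± 0.06 in Cat100-6 acid soil (SD, n = 3), and lay between 0.53 and 0.93 on the S1587-17 arrays. The dap control, an RNA spiked in before labelling, differed between the lines as well. Its means were 2.27 and 2.29 in control and acid soil in Cat100-6, and 1.44 in both soils in S1587-17. The gap between lines is therefore not read as RNA quality.

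**Figure D1:**
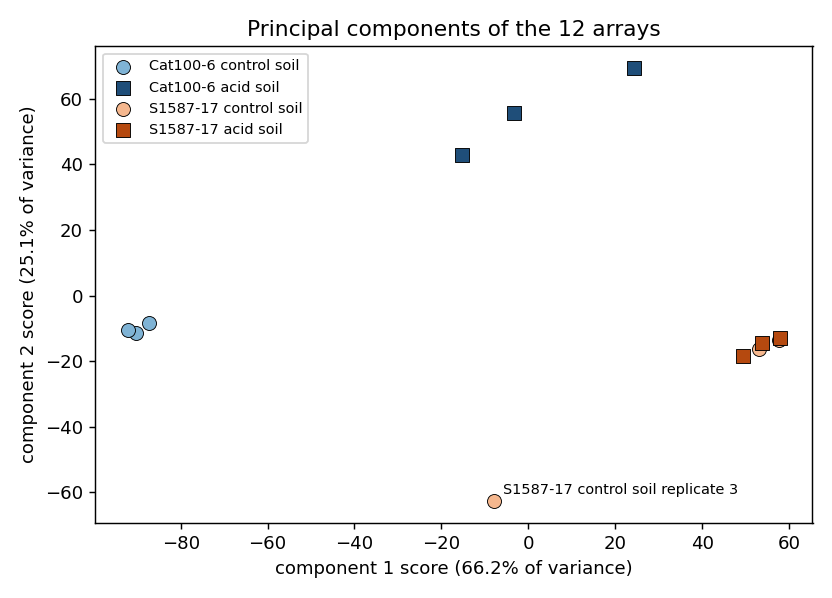
Scores of the 12 arrays on the first 2 principal components of log2 expression over 17621 probe sets; each point is an array, colours and symbols give the 4 groups, and the axes give the percentage of variance. The Cat100-6 control soil arrays lie between -92.1 and -87.4 on component 1, and S1587-17 control soil replicate 3 lies at -8.0, away from the other 2 arrays of its group at 53.2 and 57.6.

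The response of the tolerant line to acid soil was asked first. In leaves of Cat100-6, chaperones rose in acid soil at 21 of 28 probe sets, ribosomal proteins at 17 of 23 and genes of histones and cell division at 29 of 49, and growth hormone genes fell at 14 of 19 and flavonoid genes at 7 of 10. Called with a preset correlation between genes, none of these lists held its call with an estimated correlation (adjusted p = 0.722). Among named genes, each taken at its brightest probe set, the largest increase was that of glu1 (LOC542414), a β-glucosidase that releases benzoxazinoid defence compounds, from 5.71 ± 0.32 to 10.47 ± 0.32 (mean log2 expression, SD, n = 3), a 27.0-fold change (log2 difference 4.75 ± 0.86 (SE), adjusted p = 0.00122). The largest decrease among them was that of sps1 (LOC542711), a sucrose phosphate synthase, from 10.48 ± 0.35 to 6.23 ± 0.95, a log2 difference of -4.25 ± 0.49 (adjusted p = 0.000134). In total 9697 probe sets, 55% of those tested, passed in limma, 4141 of them higher and 5556 lower in acid soil. Among the named genes 267 were higher and 335 lower. A change of at least 2-fold was reached by 1824 higher and 1167 lower probe sets. The 3 arrays of each soil did not overlap at 68.6% of the probe sets, where chance gives 10%.

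Heat shock proteins and chaperones rose at 21 of 28 probe sets and fell at 4, with 3 not passing (21 higher and 4 lower when adjusted over the list alone). Their median log2 change was 1.18 (camera adjusted p = 7.79e-07, and adjusted p = 0.722 with an estimated correlation). In this list crt2, which encodes the calcium-binding chaperone calreticulin, rose by 2.92 ± 0.24 (SE) and the protein disulfide isomerase gene pdi6 by 1.37 ± 0.15, with adjusted p = 2.06e-05 and 8.64e-05. Ribosomal proteins rose at 17 of 23 probe sets and fell at 1 (18 and 1 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 3.52e-06, adjusted p = 0.722 with an estimated correlation). Here rps6-2 rose by 1.59 ± 0.19 (adjusted p = 0.000167) and rps27 by 1.23 ± 0.16 (adjusted p = 0.000207). Histones and cell division rose at 29 of 49 probe sets and fell at 3 (30 and 4 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 5.43e-06, adjusted p = 0.722 with an estimated correlation). Its members included the cyclin gene cyc3 (3.91 ± 0.93), MCM7, a subunit of the replicative helicase (3.54 ± 0.87), pcna2, the sliding clamp of DNA polymerase (3.50 ± 0.77), and the β-tubulin genes tub4 (1.35 ± 0.11) and tub6 (1.31 ± 0.15). Other large increases were those of the chromatin genes nfd101 (4.41 ± 0.93), nfd106 (4.15 ± 0.87) and hmg2 (3.56 ± 0.55), of prp2, a member of the defence list (3.83 ± 0.26) and of fps1, a farnesyl pyrophosphate synthase (3.63 ± 0.60).

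Growth hormone genes (auxin, gibberellin, cytokinin and brassinosteroid) fell at 14 of 19 probe sets and rose at 2 (15 and 2 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.0158, adjusted p = 0.722 with an estimated correlation). The cytokinin response regulator RR7 changed by -2.19 ± 0.23 and an1, an enzyme of gibberellin synthesis, by -2.55 ± 0.49, whereas the auxin-binding protein gene abp1 rose by 1.34 ± 0.15. Flavonoid and anthocyanin genes fell at 7 of 10 probe sets and rose at 0 (8 and 0 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.0358, adjusted p = 0.722 with an estimated correlation), among them fht1, the flavanone 3-hydroxylase (-2.48 ± 0.40). The call of this list ended without Cat100-6 acid soil replicate 1 (adjusted p = 0.0573) or control soil replicate 2 (adjusted p = 0.0517), with 1 probe set per gene (adjusted p = 0.0795), with a second quantile normalization (adjusted p = 0.0783) and with medians subtracted (adjusted p = 0.0592). C4 and Calvin cycle genes fell at 10 of 12 probe sets and rose at 1 (11 and 1 adjusted over the list alone), but the list as a whole did not pass camera (median -0.68, adjusted p = 0.0747). Rubisco activase (rca1) changed by -1.67 ± 0.41, the chloroplast malate dehydrogenase gene mdh6 by -0.89 ± 0.21 and the plastid glyceraldehyde-3-phosphate dehydrogenase gene gpb1 by -0.73 ± 0.14. Chlorophyll and carotenoid synthesis fell at 5 of 7 probe sets (5 adjusted over the list alone, camera adjusted p = 0.115), with pds1, the phytoene desaturase, at -1.05 ± 0.22. Photosystem and light harvesting genes fell at 3 of 11 (3 adjusted over the list alone, adjusted p = 0.2), among them psad1 of photosystem I (-0.87 ± 0.22).

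The remaining lists did not pass camera in Cat100-6. Starch and sucrose metabolism had 8 probe sets higher and 11 lower of 27, both over all genes and adjusted over the list alone (camera adjusted p = 0.764). Within it the sucrose transporter gene sut1 changed by -2.61 ± 0.46, the sucrose synthase gene sus1 rose by 1.53 ± 0.19, and Agp2, of the enzyme that makes ADP-glucose for starch, rose by 1.74 ± 0.13. Nitrogen and sulfur assimilation had 1 higher and 7 lower of 14 (1 and 7 adjusted over the list alone, adjusted p = 0.219), including the nitrate reductase gene NNR1 (-2.51 ± 0.40). Glutathione transferases were split into 10 higher and 10 lower of 35 (10 and 10 adjusted over the list alone, adjusted p = 0.749), with gst11 at 2.09 ± 0.23 and gst37 at -0.59 ± 0.09. Their median of -0.19 and mean of 0.02 differed in sign, and camera pointed up. Defence genes had 6 higher and 7 lower of 18 (6 and 8 adjusted over the list alone, adjusted p = 0.697), with a median of -0.12, a mean of 0.27 and camera pointing up. Cell wall genes had 7 higher and 9 lower of 28 (7 and 9 adjusted over the list alone, adjusted p = 0.807), with a median of -0.16 and camera pointing up. Antioxidant enzymes had 3 higher and 4 lower of 20 (3 and 4 adjusted over the list alone, adjusted p = 0.807). Jasmonate and ethylene genes had 3 and 5 of 20 (3 and 5 adjusted over the list alone, adjusted p = 0.725), and abscisic acid genes 1 and 5 of 13 (1 and 3 adjusted over the list alone, adjusted p = 0.559). Lignin genes had 0 and 2 of 5 (0 and 2 adjusted over the list alone, adjusted p = 0.250) and iron genes 0 and 3 of 10 (0 and 2 adjusted over the list alone, adjusted p = 0.435).

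Markers of other tissues and of leaf cell types were also counted. Root-preferential genes had 1 higher and 6 lower of 11 (1 and 6 adjusted over the list alone, camera adjusted p = 0.250), among them zrp4 at -1.81 ± 0.21. Seed markers had 0 higher and 7 lower of 21 (0 and 7 adjusted over the list alone, adjusted p = 0.250). Mesophyll-preferential genes had 1 and 8 of 12 (1 and 8 adjusted over the list alone, adjusted p = 0.115) and bundle sheath genes 1 and 4 of 5 (1 and 4 adjusted over the list alone, adjusted p = 0.546). Of the lists too small for camera, 0 of 2 probe sets of the aluminium list, both of asr1, passed over all genes, against 1 higher and 1 lower adjusted over the list alone. The phosphate transporter gene pht1 changed by -1.76 ± 0.27 and the other gene of its list, pht7, did not pass over all genes (1 higher and 1 lower of 2 adjusted over the list alone). The single TCA cycle probe set differed by -0.06, and by 0.04 after a second quantile normalization, and did not pass. Other large decreases were those of the xyloglucan-modifying enzyme gene xet1 (-3.16 ± 0.53), the aquaporin gene nip2b (7.99-fold lower), the laccase gene LAC1 (-2.98 ± 0.43), the peroxidase gene PER42 (-2.95 ± 0.49) and gl1, a gene of cuticular wax synthesis (-2.53 ± 0.45). All these named genes passed with each array left out in turn. The median of all probe sets changed by -0.14, and by -0.24 when each array's median was subtracted, with 3584 probe sets then higher and 7314 lower. The 3′ minus 5′ difference of the control genes also differed between the soils in this line (1.59 and 1.37). Of the 10 splits of the 6 Cat100-6 arrays into groups of 3, 7 gave at least 5 lists, the real one included.

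Controls spiked into the samples also moved with the soils of Cat100-6. The mean of 9 hybridization control probe sets was 10.21 ± 0.21 in control and 9.71 ± 0.31 in acid soil in this line, and 10.26 ± 0.05 and 10.17 ± 0.01 in S1587-17 (SD, n = 3). The dap control fell from 10.08 ± 0.01 to 9.34 ± 0.22 in Cat100-6 and lay at 8.86 ± 0.34 and 8.84 ± 0.16 in S1587-17. When each array was set to the same mean of the 9 hybridization controls, an alternative chosen after the data were seen, 7639 probe sets passed in Cat100-6, 6589 of them higher and 1050 lower, and the median of all probe sets changed by 0.36. With 2 other sets of these controls, 8595 and 8419 passed, 7801 and 7635 of them higher. Scaled to the 9 controls, chaperones rose at 23 probe sets, ribosomal proteins at 20 and histones and cell division at 36, while growth hormone genes fell at 6, flavonoids at 1 and C4 and Calvin cycle genes at 2. The medians of 14 of 25 lists turned from negative to positive, among them those of photosystems (0.28), nitrogen and sulfur assimilation (0.04), root-preferential genes (0.19) and seed markers (0.32). The decreases of psad1, mdh6, gpb1 and gst37 no longer passed. The balance of increases and decreases in this line therefore depended on the scale.

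**Figure D2:**
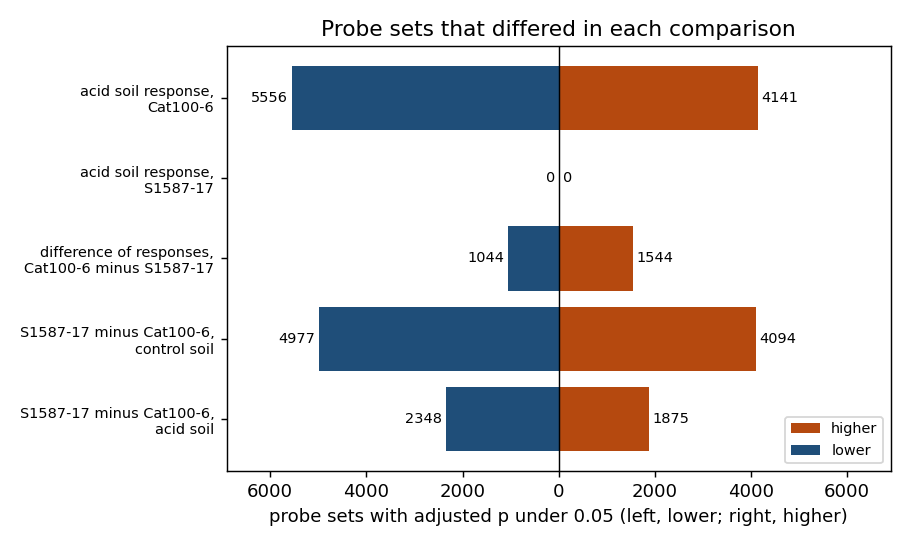
Bars give the number of probe sets with adjusted p under 0.05 in limma, lower to the left and higher to the right, in 5 comparisons among 17621 probe sets. The response of Cat100-6 had 4141 higher and 5556 lower probe sets, and that of S1587-17 had 0 of either.

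Whether the sensitive line responded to the same soil was asked next. No probe set passed in S1587-17 in limma (lowest adjusted p = 0.401), and 613 had an unadjusted p under 0.05. With array weights 2 passed, and 1 passed without control soil replicate 2 or 3 of this line or when scaled to the spiked controls. The 3 arrays of each soil did not overlap at 7.66% of the probe sets, where chance gives 10%. The named genes with the lowest p did not pass. Among them, the vacuolar aquaporin gene tip2b differed between acid and control soil by -0.80 ± 0.18 (SE), the haemoglobin gene Hb2 by -0.81 ± 0.18 and sum1 by -0.81 ± 0.16. The first benzoxazinoid enzyme, bx1, differed by 0.73 ± 0.17, phytase1 by 0.73 ± 0.24, the glutathione transferase gene gst5 by 0.47 ± 0.12 and the small heat shock protein gene hsp18f by 0.51 ± 0.16. NIR, the nitrite reductase gene, differed by -0.74 ± 0.22 and AGA2 by -0.70 ± 0.21, and without control soil replicate 3 these differences were -0.42 and -0.43. The value of pdh2 was -0.39 ± 0.09. Adjusted p-values of these 10 genes lay between 0.646 and 0.874. Levels of some were spread more widely in control than in acid soil, as with NIR (7.70 ± 0.57 and 6.95 ± 0.14) and bx1 (10.93 ± 0.42 and 11.66 ± 0.14) (SD, n = 3). For both genes control soil replicate 3 lay apart. It held 8.35 for NIR, against 7.32 and 7.42 in replicates 1 and 2, and 10.44 for bx1, against 11.15 and 11.19.

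With 0 single probe sets past the threshold, camera still called 7 lists in S1587-17. Chaperones were shifted up (median 0.23, adjusted p = 6.33e-06), as were histones and cell division (0.16, adjusted p = 0.0191) and ribosomal proteins (0.11, adjusted p = 0.0245). Growth hormone genes (-0.18, adjusted p = 0.000971), nitrogen and sulfur assimilation (-0.19, adjusted p = 0.00172), the C4 and Calvin cycle (-0.24, adjusted p = 0.0497) and mesophyll genes (-0.16, adjusted p = 0.0497) were shifted down. All 7 calls ended with an estimated correlation (adjusted p = 0.717). Those of the C4 and Calvin cycle and of mesophyll genes also ended with a second quantile normalization (adjusted p = 0.12), with medians subtracted (adjusted p = 0.0579), with either replicate block, with 1 probe set per gene and without any 1 of 7 arrays (adjusted p between 0.0511 and 0.378 over these settings). The call of histones and cell division ended without the 40% dimmest probe sets (adjusted p = 0.117) or without S1587-17 acid soil replicate 2 (adjusted p = 0.059), and that of ribosomal proteins without S1587-17 acid soil replicate 3 (adjusted p = 0.0816). No member of these lists passed either over all genes or adjusted over the list alone, and of the other lists only that of defence genes had 1 higher adjusted over the list alone. Without S1587-17 acid soil replicate 3, 4 lists were called. Without S1587-17 control soil replicate 3, none of the 7 kept its call with its direction. Chaperones then had a median of -0.02, with camera pointing up (adjusted p = 0.61). Histones and cell division had a median of -0.06 (adjusted p = 0.0365, shifted down) and ribosomal proteins one of -0.05 (adjusted p = 0.126), while glutathione transferases were shifted up (0.06, adjusted p = 0.0156). With an estimated correlation the adjusted p of histones and cell division and of glutathione transferases was 0.602. A single unnamed probe set passed, with a log2 difference of 1.20 (adjusted p = 0.0130). Across probe sets, which are not independent replicates, the responses of the lines correlated at r = 0.748, and at r = -0.05 without that array.

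**Figure D3:**
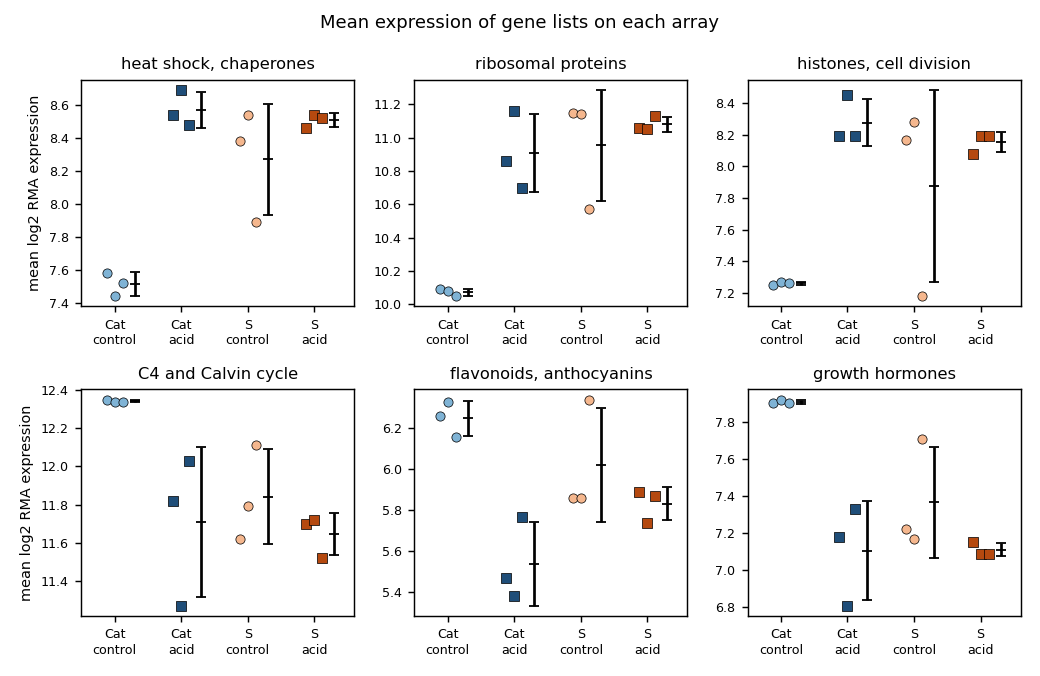
Mean log2 RMA expression over the probe sets of 6 gene lists on each of the 12 arrays, by group; points are arrays and bars give the mean ± SD of 3 arrays. Chaperones averaged 7.51 ± 0.07 in Cat100-6 control soil and 8.57 ± 0.11 in Cat100-6 acid soil, against 8.27 ± 0.34 and 8.51 ± 0.04 in S1587-17, where 1 control soil array, replicate 3, lies apart.

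The difference between the lines' responses was tested directly. The calreticulin gene crt2 changed by 2.92 in Cat100-6 and by 0.37 in S1587-17, a difference of 2.56 ± 0.34 (SE, n = 3 per group, adjusted p = 0.00171). Without S1587-17 control soil replicate 3, the S1587-17 value of crt2 was 0.05 and the difference 2.87. The sucrose phosphate synthase gene sps1 changed by -4.25 and -1.08, a difference of -3.17 ± 0.69 (adjusted p = 0.0170), and without that array the S1587-17 value was -0.64 and the difference -3.61. The sucrose transporter gene sut1 had a difference of -2.36 ± 0.65 (adjusted p = 0.0358). A total of 2588 probe sets, 14.7%, passed, 1544 with a higher and 1044 with a lower value in Cat100-6. Of the named genes 104 were higher and 63 lower. Chaperones were higher at 15 of 28 probe sets and lower at 1 (18 and 3 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 4.89e-06, adjusted p = 0.623 with an estimated correlation). The protein disulfide isomerase genes pdi (2.40 ± 0.57) and pdi6 (1.34 ± 0.21) were among them. Ribosomal proteins were higher at 11 of 23 and lower at 0 (13 and 0 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 4.89e-06, adjusted p = 0.623 with an estimated correlation), including rps6-2 (1.32 ± 0.27) and rps27 (1.09 ± 0.22). Histones and cell division were higher at 11 of 49 and lower at 0 (15 and 0 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 2.31e-05, adjusted p = 0.623 with an estimated correlation), including the tubulin genes tub4 (1.40 ± 0.16) and tua6 (1.23 ± 0.20).

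Among the highest differences of responses were those of prp2 (3.38 ± 0.36), fps1 (2.78 ± 0.85) and hmg2 (2.76 ± 0.77), followed by crt2, thi2 (2.55 ± 0.38), lbl1, a gene of the small RNA pathway that patterns leaves (2.53 ± 0.74), pdi and AGPLS3, a large subunit of the starch enzyme ADP-glucose pyrophosphorylase (1.98 ± 0.46). The lowest were those of sps1, xet1 (-2.44 ± 0.75), nip2b (-2.42 ± 0.70), sut1, the pyruvate dehydrogenase kinase gene pdlk2 (-2.27 ± 0.55), chn1 (-2.17 ± 0.64), LAC1 (-2.14 ± 0.61), the potassium channel genes kch4 (-2.09 ± 0.28) and kch3 (-2.02 ± 0.52) and fht1 (-1.91 ± 0.57). Adjusted p-values of these genes lay between 0.000682 and 0.0499. The calls of prp2, crt2, thi2, pdi6, rps6-2, rps27, tub4 and tua6 held under every alternative. That of kch4 held wherever it was tested, which the filter on dim probe sets did not do. Those of the other genes in this paragraph ended when at least 1 array was left out or under another alternative. The count depended on S1587-17 control soil replicate 3: without it 7920 probe sets passed, 3627 higher and 4293 lower, and 6 lists, with growth hormone genes (-0.57, adjusted p = 0.0310), chlorophyll and carotenoid synthesis (-0.73, adjusted p = 0.0310) and flavonoids (-0.55, adjusted p = 0.0469) added. Histones and cell division were then higher at 29 of 49 probe sets, ribosomal proteins higher at 17 and lower at 1 of 23, and chaperones higher at 19 and lower at 4 of 28. The 3 added lists had an adjusted p = 0.549 with an estimated correlation. Without any other array than this and Cat100-6 acid soil replicate 3, the count fell to between 967 and 1306. The share of higher probe sets was 59.7%, and 43.9% when each array's median was subtracted (1365 higher and 1745 lower). Scaled to the 9 spiked controls, 2173 probe sets passed, 2000 higher and 173 lower, and the medians of 17 of 25 lists turned from negative to positive, with growth hormone genes at 0.08 and flavonoids at 0.02.

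**Figure D4:**
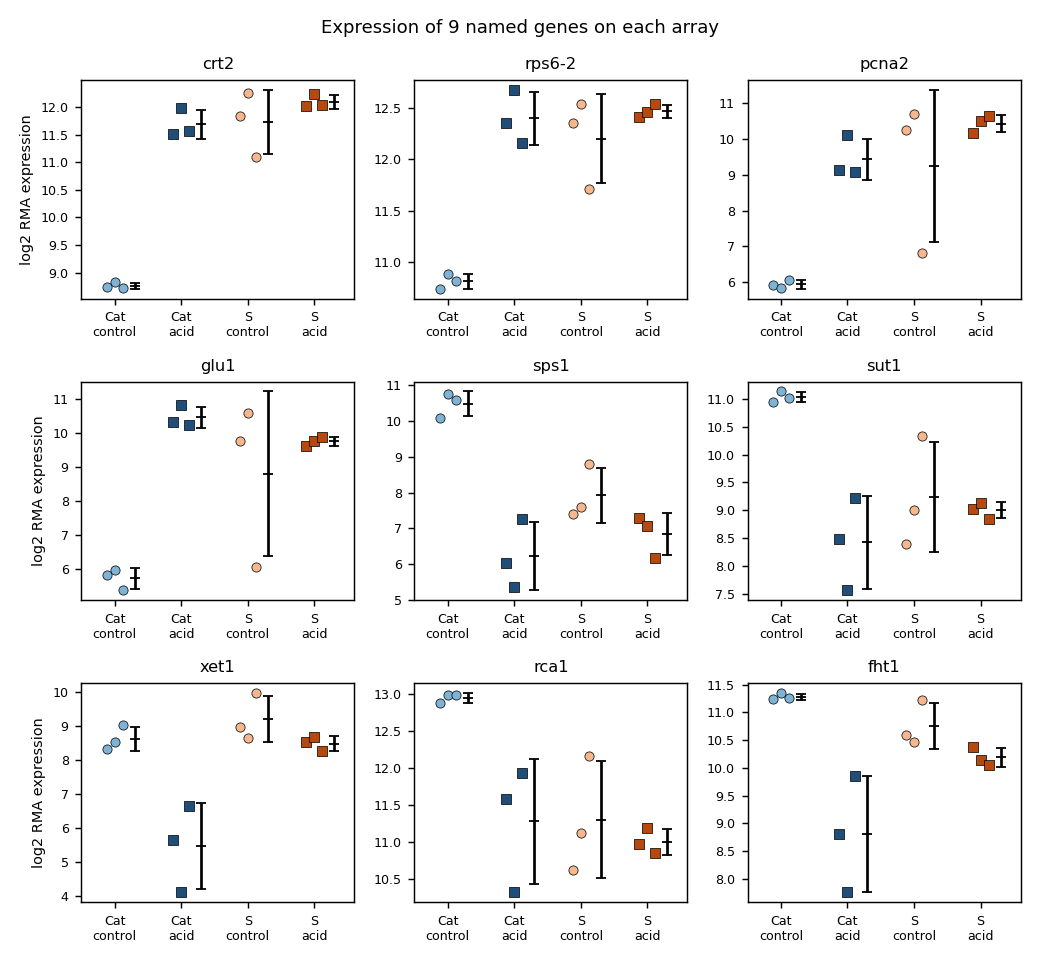
Log2 RMA expression of 9 named genes on each of the 12 arrays, by group; points are arrays and bars give the mean ± SD of 3 arrays. The calreticulin gene crt2 averaged 8.77 ± 0.05 in Cat100-6 control soil and between 11.69 and 12.09 in the other 3 groups, and xet1 averaged 5.47 ± 1.28 in Cat100-6 acid soil and between 8.49 and 9.21 in the others.

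The lines were then compared within each soil. In control soil, S1587-17 leaves had higher values at the probe set of Lhcb5-2, named as a light-harvesting protein (log2 difference 4.82 ± 0.10 (SE), n = 3 per group, adjusted p = 9.44e-11), and at that of the plasma membrane aquaporin gene pip2b (4.05 ± 0.22, adjusted p = 1.83e-07), and lower values for the pyruvate decarboxylase gene pdc2 (-5.39 ± 0.21, adjusted p = 1.31e-08) and the catalase gene cat2 (-3.81 ± 0.40, adjusted p = 2.46e-05). Of the 3 other probe sets of pdc2, 1 differed from it in call or direction. A total of 9071 probe sets, 51.5%, passed, 4094 higher and 4977 lower in S1587-17, and without S1587-17 control soil replicate 3 this number was 10804, with 8782 of the 9071 among them. Chaperones were higher at 18 of 28 probe sets and lower at 4 (20 and 4 adjusted over the list alone, median 0.82, camera adjusted p = 0.00165), with crt2 at 2.96 ± 0.24 and the small heat shock protein gene hsp18 at -2.74 ± 0.27. Ribosomal proteins were higher at 17 of 23 and lower at 0 (18 and 0 adjusted over the list alone, median 1.08, adjusted p = 1.61e-05), with RPL10 at 0.94 ± 0.12. Histones and cell division were higher at 27 of 49 and lower at 3 (29 and 4 adjusted over the list alone, median 0.79, adjusted p = 0.00264), with pcna2 at 3.31 ± 0.77 and tub4 at 1.66 ± 0.11. These 3 lists had an adjusted p = 0.906 with an estimated correlation. Without that array they kept their calls, with histones and cell division higher at 33 and lower at 8 of 49 probe sets. Chlorophyll and carotenoid synthesis was then also lower (7 of 7 probe sets, adjusted p = 0.0158, and adjusted p = 0.765 with an estimated correlation). The tolerant line's response, the difference of responses and this comparison all use that line's control soil arrays. Their calls of the 3 higher lists are therefore not separate results. Chaperones averaged 7.51 on those arrays, against 8.57 in that line's acid soil and 8.27 and 8.51 in S1587-17 control and acid soil. Ribosomal proteins averaged 10.07, against 10.91, 10.95 and 11.08 in the same order. Histones and cell division averaged 7.26, against 8.28, 7.88 and 8.15.

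In acid soil 4223 probe sets passed, 24% of those tested, 1875 higher and 2348 lower in S1587-17. The share of higher probe sets was 44.4%, and 52% when each array's median was subtracted. Scaled to the 9 spiked controls, 6866 probe sets passed, only 528 of them higher, and the medians of 16 of 25 lists turned from positive to negative, with ribosomal proteins at -0.30 and histones and cell division at -0.34. Among named genes, Lhcb5-2 (5.21 ± 0.10, adjusted p = 6.54e-11), pip2b (4.16 ± 0.22), the histone gene his2b5 (3.77 ± 0.64) and gst42 (3.73 ± 0.47) were the highest, and pdc2 (-5.07 ± 0.21), prpo1 (-3.70 ± 0.29) and the malate synthase gene mas1 (-2.77 ± 0.20) the lowest. The other probe sets of pdc2 differed from it in call or direction in 2 of 3 cases. None of the 3 lists called in control soil passed here: chaperones were higher at 5 and lower at 4 of 28 probe sets (5 and 4 adjusted over the list alone, median -0.06, adjusted p = 0.944), ribosomal proteins higher at 1 and lower at 0 of 23 (0 and 0 adjusted over the list alone, 0.16, adjusted p = 0.583) and histones and cell division higher at 4 and lower at 4 of 49 (1 and 2 adjusted over the list alone, adjusted p = 0.956), with a median of 0.11, a mean of -0.12 and camera pointing down. Without S1587-17 control soil replicate 3, which is not itself in this comparison, histones and cell division were higher at 7 and lower at 9 with camera pointing up (adjusted p = 0.924). Ribosomal proteins were then higher at 3, and chaperones higher at 6 and lower at 6. No list passed camera in acid soil (lowest adjusted p = 0.583).

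Some single genes separated the lines in both soils. The alternative oxidase gene aox1 was lower in S1587-17 by a log2 difference of -1.91 ± 0.11 in control and -1.64 ± 0.11 in acid soil, gst10 by -1.69 ± 0.11 and -1.92 ± 0.11, and the lignin gene cad2 by -2.22 ± 0.27 and -1.86 ± 0.27. The iron storage gene fer1 was lower by -0.77 ± 0.09 and -0.58 ± 0.09 and crtRB1, a carotene hydroxylase, by -1.28 ± 0.24 and -1.30 ± 0.24. The terpene synthase gene tps4 was higher by 2.21 ± 0.22 and 1.90 ± 0.22, and the expansin gene expa2 by 1.65 ± 0.28 and 1.74 ± 0.28. Higher in S1587-17 in both soils were 1247 probe sets, where independent calls would share 436, and lower in both were 1807, where 663 would be shared, and 74 went opposite ways. The 2 comparisons share no array, but they share the residual variance of each probe set, so their calls are not independent. The dap control, an RNA spiked in before labelling, also separated the lines, with a 3′ minus 5′ difference of 2.18 to 2.36 on Cat100-6 and 1.32 to 1.55 on S1587-17 arrays (n = 6 per line, exact permutation p = 0.00216, two-sided). Line and labelling could not be told apart, and probe sets of a gene went the same way less often for the line difference in acid soil (62.5%) than for the response of Cat100-6 (85.5%).

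Averaged over both lines, 8252 probe sets passed, 46.8%, with 3782 higher and 4470 lower in acid soil (3193 and 6147 when each array's median was subtracted). This average leans on Cat100-6, since 0 probe sets passed in S1587-17 alone. Across probe sets the log2 changes had an SD of 0.236 in S1587-17, against 0.862 in Cat100-6. The average is therefore not read as a response shared by both lines. Scaled to the 9 spiked controls, 6311 passed, 5536 higher and 775 lower, and growth hormone genes fell at 5 probe sets, C4 and Calvin cycle genes at 2 and flavonoids at 1. Chaperones rose at 21 of 28 probe sets and fell at 1 (21 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 8.83e-08), ribosomal proteins at 18 of 23 and 1 (18 and 1 adjusted over the list alone, 0.58, adjusted p = 6.94e-06) and histones and cell division at 29 of 49 and 3 (29 and 3 adjusted over the list alone, 0.54, adjusted p = 7.96e-06). Growth hormone genes fell at 11 of 19 and rose at 1 (12 and 1 adjusted over the list alone, -0.33, adjusted p = 0.00467), flavonoids fell at 6 of 10 (6 adjusted over the list alone, -0.34, adjusted p = 0.0388) and C4 and Calvin cycle genes fell at 10 of 12 and rose at 1 (10 and 1 adjusted over the list alone, -0.47, adjusted p = 0.0472). Without S1587-17 control soil replicate 3, 7387 probe sets passed. All 6 lists had an adjusted p = 0.816 with an estimated correlation. The C4 and Calvin cycle list did not pass with a second quantile normalization (adjusted p = 0.107), with medians subtracted (adjusted p = 0.0816), with either replicate block (adjusted p = 0.0664 and 0.0575) or without any 1 of 6 arrays (adjusted p between 0.0527 and 0.0882). These were each control soil replicate of Cat100-6 and control soil replicates 2 and 3 and acid soil replicate 3 of S1587-17. The flavonoid list did not pass with a second quantile normalization (adjusted p = 0.0943), with medians subtracted (adjusted p = 0.0591), or with 1 probe set per gene (adjusted p = 0.0718). It also did not pass without Cat100-6 acid soil replicate 1, Cat100-6 control soil replicate 2 or replicate 2 of either soil of S1587-17 (adjusted p between 0.0502 and 0.0551).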

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

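The tests of the unusual array, of array scaling, of growth stage and of labelling were chosen after the results were seen, and those of RNA quality as a cause of the Cat100-6 response and of probe sequence were chosen before.

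The responses of the lines to acid soil differed, by the test of the difference itself, at 2588 probe sets and in 3 lists, with medians of 0.95 for chaperones, 0.95 for ribosomal proteins and 0.77 for histones and cell division (all 3 lists had an adjusted p = 0.623 with an estimated correlation). Among named genes the difference was 3.38 for prp2, 2.78 for fps1, 2.76 for hmg2, 2.56 for crt2, 2.55 for thi2, 2.53 for lbl1, 2.40 for pdi, 1.98 for AGPLS3, 1.40 for tub4, 1.34 for pdi6, 1.32 for rps6-2, 1.23 for tua6 and 1.09 for rps27. It was -3.17 for sps1, -2.44 for xet1, -2.42 for nip2b, -2.36 for sut1, -2.27 for pdlk2, -2.17 for chn1, -2.14 for LAC1, -2.09 for kch4, -2.02 for kch3 and -1.91 for fht1.

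Other divisions of the samples bear on these counts. For the difference of responses, 8 of 100 divisions of the soils within lines gave at least 2588 probe sets, the highest of the others 8665. All 8 were among the 9 that kept the Cat100-6 soils apart. Such divisions keep the Cat100-6 response, so their share does not measure chance for this count, and chance cannot be excluded. The highest other count points to a structure of the samples whose cause was not tested. For its 3 lists, 62 of 100 gave as many, with up to 11, and chance cannot be excluded. For the mean response, 4 of 100 gave at least 8252 probe sets (highest other 8655), a share under 0.05. All 4 were among the 9 divisions that kept the Cat100-6 soils apart, so the low share rests on the Cat100-6 soils. The Cat100-6 arrays alone allow only 10 divisions, so chance is not excluded for a response of both lines. For the lists, 28 of 100 gave at least 6 (up to 10), so chance cannot be excluded there either. The 6 arrays of a pair of groups allow 10 divisions, too few for a share under 0.05. Counts as large came from 1 of 10 for the Cat100-6 response (9697, highest other 0), 10 of 10 for S1587-17 (0, highest other 1), and 1 of 10 for the line difference in control soil (9071, highest other 0) and in acid soil (4223, highest other 0). Lists as many came from 7 of 10 for Cat100-6 (5, highest other 9), 3 of 10 for S1587-17 (7, highest other 8), 4 of 10 for the lines in control soil (3, highest other 7) and 10 of 10 in acid soil (0, highest other 9).

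S1587-17 control soil replicate 3 stood apart from its group. A mixture with, or a mislabelled sample of, Cat100-6 is argued against: at 33 probe sets over 3 log2 units higher in Cat100-6 than in S1587-17 in acid soil, and little changed by soil, it reached a median of 0.001 of the Cat100-6 level (upper quartile 0.033), against 0.259 (lower quartile 0.197) at 60 probe sets that fell in Cat100-6 in acid soil. Degraded RNA is argued against by its 3′ minus 5′ difference of 0.70, within the 0.53 to 0.93 of the other S1587-17 arrays. A candidate explanation is a leaf state shared with the Cat100-6 control plants, such as age, hour of harvest or handling, since its deviation followed the Cat100-6 control minus acid difference, on other arrays, at r = 0.82 across probe sets. The array had already stood out by its likeness to Cat100-6 control soil, so this correlation in part restates that likeness. No clock gene was among the named probe sets, so the hour was not tested apart.

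In Cat100-6 9697 probe sets passed and in S1587-17 none did. RNA quality as the whole cause was not settled. The change predicted from the 3′ to 5′ ratio of the other S1587-17 arrays had a slope of 0.022 on the observed one. All 120 orders of these 5 arrays gave slopes of -0.041 to 0.044, so none could come near 1. Their ratios, 0.53 to 0.93, also lay below the 1.31 to 1.68 of the Cat100-6 arrays. The values show only that ratios within the S1587-17 range went with little of the Cat100-6 change. Array scaling as the cause of the count is argued against by at least 7639 probe sets under 3 other scalings, the lowest of them with each array set to the same mean of 9 spiked hybridization controls. For the balance of directions it stays open: these controls were lower in acid soil in Cat100-6 (9.71 against 10.21), and scaled to them 6589 of the 7639 were higher, against 4141 of 9697. Of the 9697 probe sets, 5191 passed again with the same sign when scaled to these controls. The count alone therefore does not show that the same probe sets passed. A growth stage or harvest particular to the Cat100-6 control plants cannot be told apart from soil. An S1587-17 control soil sample, replicate 3, showed part of the same profile, with a slope of 0.64, and no record of stage is in the labels. A response of the tolerant line to acid soil stays open beside it.

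Between 24% and 51.5% of probe sets separated the lines. Labelling of the lines in different batches cannot be told apart from line, because the spiked-in control separates exactly the same arrays (exact permutation p = 0.00216). Probe sequence differences may account for part of it, since the share of same-direction probe sets differed from that of the Cat100-6 response by -23 percentage points (62.5% against 85.5%, 95% interval -48.3 to -1.8), from 9 genes. Differences in expression between the lines stay open as well.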

How the results depend on the processing

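The scaling to 9 spiked hybridization controls was chosen after the results were seen, and the other alternatives before. It gave 6866 probe sets for the lines in acid soil and 1 for S1587-17, and 10 lists for Cat100-6 and 5 for the lines in control soil. It turned PP2C and glb3 in Cat100-6 to 0.066 and 0.042 and RPL10 and glb3 between lines in acid soil to -0.079 and -0.125, because it lowers or raises all values of an array alike. Named genes and called lists kept their direction under every other alternative that tested them except without S1587-17 control soil replicate 3, which turned the correlation of the responses to -0.05 and the S1587-17 medians of ribosomal proteins, of histones and cell division and of chaperones to -0.05, -0.06 and -0.02, against up to 0.25 and 0.29 for the first 2 without other arrays; the cause was not tested. Among lists that were not called, some medians near 0 changed sign with a second quantile normalization, such as the TCA cycle in Cat100-6 (-0.06 to 0.04) and glutathione transferases between lines in control soil (0.01 to -0.04). The share of higher probe sets among those passing crossed 50% for Cat100-6 (42.7% to 50.7%) and the mean (45.8% to 53.3%) with the dim filter, and reached 86.3% and 87.7% with the spiked controls (92% for the difference, 7.69% for the lines in acid soil). It also crossed 50% for the lines in acid soil (44.4% to 52%) with medians subtracted, and for the difference (59.7%) with medians subtracted (43.9%), array weights (46.5%) and without that array (45.8%). Requiring a change of at least 2-fold left 2991 probe sets for the Cat100-6 response, 1328 for the difference of responses, 3430 and 1221 for the lines in control and acid soil and 1056 for the mean, by construction. Array weights gave 2 for S1587-17 and 7381 for the difference. An estimated correlation left 0 lists for either line, their difference, the lines in control soil and the mean. With each array left out, the counts ranged from 0 to 1 for S1587-17 and from 967 to 7920 for the difference, where 11 of 12 arrays moved it by over 1.5 times. Lists ranged from 2 to 7 for S1587-17 (2 without control soil replicate 3, 4 without acid soil replicate 3) and from 3 to 6 for the difference, and the correlation of the responses from -0.05 to 0.797. For Cat100-6 the range was 7731 to 10939, for the lines 7455 to 10804 in control and 2923 to 5932 in acid soil, and for the mean 6529 to 8836, all within 1.5 times. Fewer arrays leave less power, and no other cause was tested. The replicate numbers did not pair the arrays: 5 of 18 same-number pairs deviated together at r over 0.1 (range -0.29 to 0.68), and 6 of 12 arrays correlated best with their own number. With the number as a replicate block within line the difference had 1193 probe sets, against 3494 with a block shared by all groups, and no other count moved by over 1.5 times with either. Named genes of Cat100-6 changed call only under the 2-fold threshold (13 of 57) and with the spiked controls (10 weaker, 2 reversed), and those of the difference in 220 of 484 cases of another array left out, in 21 of 44 with the block within line, in 8 with the spiked controls, in 6 under the 2-fold threshold and in 3 with a second quantile normalization. Those between lines changed under that threshold in 18 of 64 in control and 15 of 49 in acid soil. Another array left out changed 27 of 704 and 52 of 539 cases, and any other alternative at most 4 and 8 genes. Low signal limits dim probe sets: leaving out the 40% dimmest kept 6849 of the 9697 Cat100-6 calls, with fewer probe sets tested. It tested 50 of the 57 named genes of Cat100-6, 36 of 44 of the difference, 52 of 64 and 37 of 49 between lines in control and acid soil, and not the flavonoid list of Cat100-6 and the mean.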

Other observations

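The family tests below were chosen after the values were seen, with the families defined by gene symbol.

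Genes of chromatin proteins, as defined by symbol, rose in Cat100-6 leaves in acid soil at 30 of 68 probe sets and fell at 4, with a median log2 change of 0.34 (0.28 with a second quantile normalization, 0.24 with medians subtracted and 0.83 scaled to the spiked controls). The 4 include MNB1a (-0.95 ± 0.30, SE), whose symbol alone does not show that it encodes a chromatin protein. Beside the genes named in the report, met5, named as a DNA methyltransferase, rose by 2.76 ± 0.78 (SE, n = 3, limma adjusted p = 0.0121; 1 of its 3 other probe sets did not), the histone deacetylase gene hdt103 by 2.01 ± 0.61 (1 of its 3 other probe sets did not), the chromatin assembly genes nfc104 by 2.66 ± 0.62, nfa101 by 2.18 ± 0.38 and nfc101 by 2.10 ± 0.34, and the DNA methyltransferase gene dmt106 by 1.22 ± 0.19. The acetyltransferase gene hac108 changed by -0.79 ± 0.12 and the deacetylase gene hda101 by -0.61 ± 0.17. For MNB1b, another HMG protein, a dimmer probe set rose by 7.29 ± 0.80, the widest change of the family, and the other 2 changed by -0.01 and 0.08 and did not pass. As a hypothesis, the family may have shifted as a whole: without the genes named by the rule the camera p was 6.82e-05 in Cat100-6, but with an estimated correlation it was 0.225. In S1587-17, where no probe set passed, the camera p was 9.22e-09, also upward, and 0.0942 with an estimated correlation. For the difference of responses, again without the genes named by the rule, the camera p was 0.0119, higher in Cat100-6, and 0.43 with an estimated correlation. The family was not tested without S1587-17 control soil replicate 3. Whether its shift was particular to Cat100-6 therefore stays open.

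Aquaporins, the water channels, went both ways, with 6 of 30 probe sets higher and 12 lower: nip1a rose by 2.05 ± 0.15 and PIP1-3 by 0.52 ± 0.10 (1 of its 4 other probe sets did not), while pip1e changed by -2.13 ± 0.41, tip2b by -1.90 ± 0.18 and pip2f by -1.36 ± 0.17. The median of the family turned from -0.13 to 0.36 when scaled to the spiked controls. A shift of that family was not found (limma's camera p of 0.938 without the genes named by the rule).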
